A study of Rattus norvegicus with 4 samples.

How the data were processed

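The series holds 4 one-colour arrays of NR8383 cells exposed to 9.25 µg/mL NiZnFe2O4 for 4 h, with 1 array per biological replicate. Per the labels' protocols, cells were seeded 48 h ahead in medium with 15% serum, RNA had an integrity number above 7.5, and 100 ng of it was amplified and labelled with Cy3. The labels put all 4 samples in 1 group and number the replicates. No array of the untreated cells that the design names was analysed here, so no test between groups was made. No paired analysis applies with 1 group. The headers put all 4 arrays on 1 slide with 1 scan time, so slide cannot act as a batch within these data.

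The arrays were extracted by the authors with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. The deposited values are intensities on a linear scale: a processed signal per spot and the raw median signals of the spot and of its background. The file headers report statistics of a spatial trend fitted within each array. The header value for the root mean square of that fit was 0.080 on replicate 2. It was 0.030, 0.034 and 0.049 on replicates 1, 3 and 4. The quality verdict in the headers was ExtractionEvaluate for replicates 2 and 4 and ExtractionInRange for replicates 1 and 3. What set these verdicts was not examined. The processed signal has no negative values although the background-subtracted signal has, so low values sit at a floor and have no order. The deposited processed signals are not scaled between arrays, since their 75th percentiles differ. The deposited spot flags, coded 0 or 1, mark spots well above background, spots positive and significant against background, outlier spots and saturated spots.

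Control spots (4259 per array) and spots with an outlier flag (between 491 and 828 per array) were left out. Spots of 1 probe were averaged on the log2 scale, giving 45598 probes, and a probe counted as well above background on an array when at least 0.5 of its remaining spots did. The files give an accession but no gene name per probe. Accessions without versions were looked up among the RefSeq transcripts of the rat assembly GRCr8, which gave 21109 probes with 1 symbol, 24489 with none and 0 with several. Unmatched probes, many with Ensembl or withdrawn accessions, are unnamed here and not without a gene. The array design names the genome build rn4, so no coordinates are given. Older symbols were updated through the synonyms of the same table.

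The log2 processed signal was scaled by subtracting the 75th percentile over all probes of each array. The level of a gene is that of its probe with the highest mean; of 3658 genes with 2 or more probes, 907 had probes that disagreed on being above background. A gene counted as well above background if any of its probes did on all 4 arrays. A gene that did not has only an upper bound, and the number of arrays on which it passed is given in place of a level. Signals of different probes depend on the probe sequence, so levels of different genes are not set against each other. Only 25.4% of probes were well above background on all 4 arrays, so the 75th percentile over all probes lies near background; the same percentile over these probes was an alternative, and the 2 scalings differed by at most 0.08 log2 units on an array.

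For 18 gene lists fixed before the data were examined, the share of measured members above background was compared with all other genes with a symbol by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Genes of a list are not independent and the other genes include many restricted to other tissues, so these p-values describe the lists on these arrays. The spread of a list was placed among 10000 random lists of the same size, matched on signal in 20 bins, by its median gene SD and by the SD between arrays of its mean. Genes are named by 2 rules set in advance: members chosen per list for their known role, and genes from the 10 with the largest SD among genes above background. Not every gene that meets a rule is named. Members outside these rules are named only to spell out a count or because their spot lies in an area of lowered signals, after their values were seen.

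Alternatives were the looser background flag, 3 of 4 arrays, all probes of a gene, quantile normalization, no scaling, centring on 7 spike-in probes, the percentile over detected probes, the mean of all probes, no filter on dim probes, and leaving out each replicate. Slide as a block was not run, as there is 1 slide. The planned normexp correction needed the mean spot signal; it was run on the median signal with an offset of 50 (limma 3.58.1, R 4.3.3), an alternative added after seeing the files. The removal of a local trend over 10 rows and columns, the restriction to probes in 10 spots and 6 further gene lists were also added after seeing the data. All else ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated data for the 6418 genes. Of 200 genes given an SD of 1, 87.5% were found above 0.5, against 0.129% of other genes. Those other genes had a noise SD of 0.2 and included the genes of the shifted lists. On the real arrays the SD per gene had a median of 0.23 and a 90th percentile of 0.43. The 0.129% is therefore no error rate for these arrays. Of 40 lists of 20 genes shifted by 0.3 on 1 array 87.5% lay outside the random lists by their mean, against 5% of unchanged lists. The simulated noise was independent between genes. On the real arrays, random lists matched to the heat shock (10 genes), macrophage (20) and proteasome (36) lists had median list-mean SDs of 0.094, 0.080 and 0.086. Independent noise would fall more with list size, so the 87.5% may not hold on these arrays. By gene SD 12.5% of unchanged lists lay outside, more than the 5% the limits allow. In that simulation the random lists also drew on the genes given a wider spread, which the unchanged lists left out. The 12.5% is therefore no error rate for lists on these arrays, and none is known for the lysosome call.

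Biological replicates are stated by the design text. No file gives read depth for arrays; precision rests on 4 arrays, on the signal over background and on the number of spots per probe. Probes printed in 10 spots had a median SD of 0.17 between arrays and of 0.06 to 0.10 within an array, and single-spot probes 0.25 between arrays.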

Results

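Messenger RNA levels were measured in NR8383 cells, a macrophage line that was started from cells washed out of the lung of a normal rat and that grows partly attached and partly floating. The cells had been passaged 20 times and were exposed to NiZnFe2O4, by its formula a mixed oxide of nickel, zinc and iron, at 9.25 µg/mL for 4 h. Total RNA of 4 biological replicates was labelled with the green dye Cy3 and hybridised to 4 one-colour Agilent arrays, 1 array per replicate. The design sets exposed cells against untreated cells. Arrays of untreated cells were not analysed here, so the values below describe which transcripts the exposed cells held, at what signal and with what spread between replicates, and no value shows what the exposure changed.

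Each array held 58717 spots for rat transcripts, of which 24981, 23827, 21812 and 22064 were well above background on replicates 1 to 4. No such spot was saturated. Over spots, the 75th percentile of the signal ranged from 130 to 229 intensity units. The 75th percentile over probes, after averaging the spots of a probe, was lower, at 4.55 to 5.38 on the log2 scale. Levels are given on the log2 scale relative to this percentile over the probes of the same array. The number of arrays limits their precision. Of 16581 genes with a symbol, 6418 (38.7%) were well above background on all 4 arrays, 8527 on no array and 1636 on 1 to 3 arrays. Across these 6418 genes Pearson's r between pairs of arrays lay between 0.975 and 0.986; genes are not independent replicates. No pair of arrays had identical values.

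Most macrophage markers were found in the exposed cells. Of 29 measured macrophage markers 20 were well above background on all 4 arrays, against 38.7% of the other genes (Fisher's exact test, two-sided, adjusted p = 0.00335). Cd68, a lysosomal glycoprotein of macrophages, stood at a log2 level of 7.13 ± 0.08 (SD, n = 4). Lyz2, which encodes lysozyme, stood at 9.43 ± 0.21 (SD, n = 4), and Csf1r, the receptor for the macrophage growth factor CSF1, at 0.95 ± 0.29 (SD, n = 4). The scavenger receptor genes Marco and Cd163 were not well above background on any array. The same held for Adgre1, for the complement genes C1qa, C1qb and C1qc and for Csf2rb, and the receptor genes Mrc1 and Msr1 passed on 3 of 4 arrays.

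Markers of other cell types were mostly not well above background. Of 15 measured lung epithelial markers 1 passed on all 4 arrays, the transcription factor gene Foxj1 (Fisher's exact test, adjusted p = 0.0225), while the surfactant gene Sftpc, Epcam and Scgb1a1 passed on none. Of 13 granulocyte and mast cell markers 1 passed, the antimicrobial peptide gene Camp (exact test, adjusted p = 0.0326; 0.0939 when all probes of a gene had to pass), and the neutrophil genes S100a9 and Cxcr2 passed on no array. None of 16 liver and neuron genes passed (exact test, adjusted p = 0.00123), among them Alb, Apoa1 and Syn1. Of 11 lymphocyte markers Lck and Pax5 passed, and the difference from the other genes was not past the threshold (exact test, adjusted p = 0.249). Cd3e passed on no array. Of 14 fibroblast and endothelial markers 4 passed, Dcn, Cdh5, Vwf and Pecam1 (exact test, adjusted p = 0.586). Pecam1, which leukocytes share with endothelium, stood at 1.80 ± 0.23 (SD, n = 4) and Cdh5 at -0.03 ± 0.20 (SD, n = 4), while the collagen gene Col1a1 passed on no array. The Cdh5 spot lay in an area of the replicate 2 array with lowered signals, described further on.

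**Figure D1:**
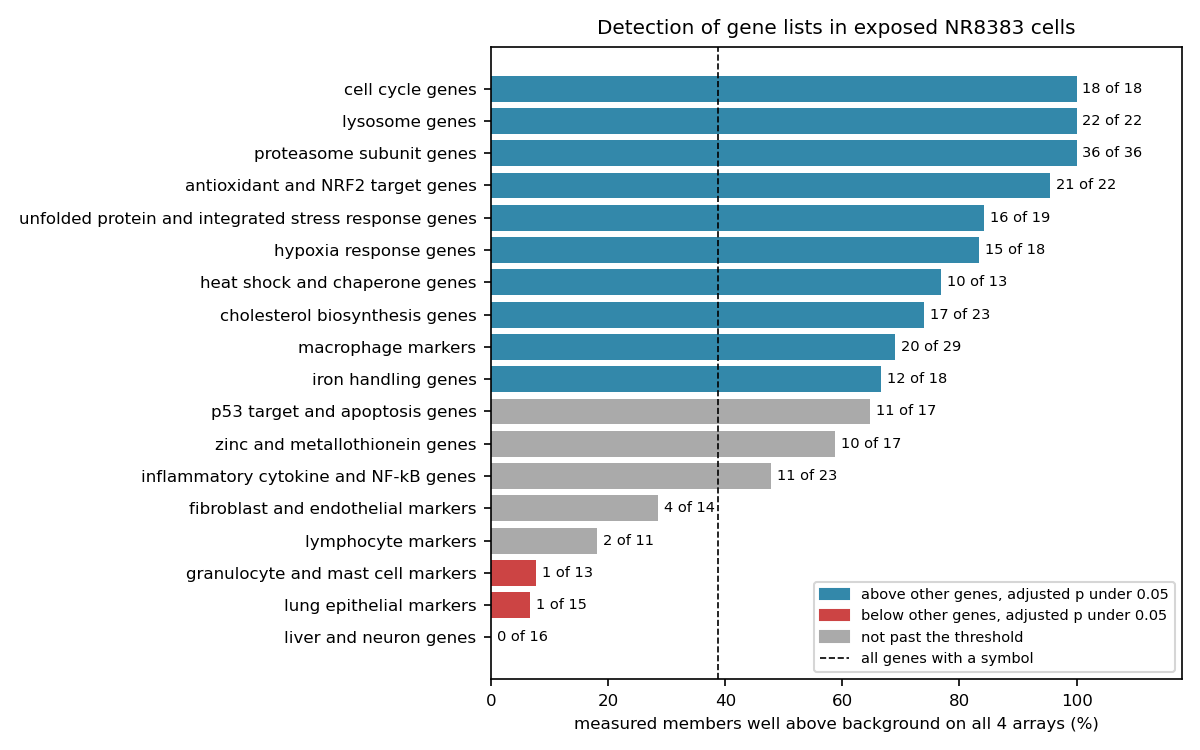
Horizontal bars give, for each of the 18 gene lists fixed in advance, the percentage of measured members that were well above background on all 4 arrays, with the numbers beside the bars. The dashed line marks the 38.7% of all genes with a symbol; 10 lists lie above the other genes and 3 below them at an adjusted p under 0.05 by Fisher's exact test.

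Transcripts of genes that handle zinc and iron were examined next. Of 17 measured zinc and metallothionein genes 10 were well above background on all 4 arrays, against 38.7% of the other genes. This difference was not past the threshold (Fisher's exact test, adjusted p = 0.159). In the 7 alternatives run for it the adjusted p of the exact test lay between 0.0505 and 0.165. The lower value was found when all probes of a gene had to pass and the higher without replicate 4. Mt1 and Mt2A, which encode metal-binding metallothioneins, stood at 7.17 ± 0.17 and 3.38 ± 0.17 (SD, n = 4 each). Slc30a1, a zinc exporter of the plasma membrane, stood at 2.79 ± 0.21 (SD, n = 4), and Mtf1, the zinc-sensing transcription factor of metallothionein genes, passed on 3 of 4 arrays, all except replicate 2. Its spot lay in the area of lowered signals on that array, and without replicate 2 the list had 11 members above background (exact test, adjusted p = 0.0520). Of 18 iron handling genes 12 passed (exact test, adjusted p = 0.0362), a call that was lost when 3 of 4 arrays sufficed (adjusted p = 0.0722). Fth1, the heavy subunit of the iron store ferritin, stood at 11.06 ± 0.17 (SD, n = 4). Tfrc, the transferrin receptor, stood at 4.16 ± 0.27 and Slc11a1, a metal transporter of the phagosome, at 4.39 ± 0.56 (SD, n = 4 each). Slc40a1, the iron exporter ferroportin, passed on no array. Probes for metallothionein and ferritin transcripts can bind near-identical family members and pseudogene transcripts, so these levels are uncertain in that respect.

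Antioxidant genes were nearly all present. Of 22 antioxidant and NRF2 target genes 21 were well above background on all 4 arrays (Fisher's exact test, adjusted p = 1.69e-07). Hmox1, the haem-degrading enzyme heme oxygenase 1, stood at 7.32 ± 0.28 (SD, n = 4), Srxn1, which repairs oxidised peroxiredoxins, at 5.56 ± 0.40 and the quinone reductase gene Nqo1 at 0.27 ± 0.05 (SD, n = 4 each). The remaining gene, Gclm, the regulatory subunit of glutathione synthesis, passed on no array and had 1 probe.

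Inflammatory genes divided into those that were measurable and those that were not. Of 23 cytokine and NF-kB genes 11 were well above background on all 4 arrays, 3 on some and 9 on none. The difference from the other genes was not past the threshold (Fisher's exact test, adjusted p = 0.419). The chemokine gene Ccl3 stood at 7.27 ± 0.10 (SD, n = 4), Il1b at 4.15 ± 0.12, Tnf at 3.67 ± 0.25 and Cxcl2 at 3.26 ± 0.40 (SD, n = 4 each). Il6 passed on no array, and Nos2, the inducible nitric oxide synthase of macrophages, passed on 2 of 4. The second of 2 Tnf probes was not well above background on all 4 arrays.

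Genes of protein turnover and folding were well represented. All 36 proteasome subunit genes were well above background on all 4 arrays (Fisher's exact test, adjusted p = 2.45e-14). Psma1 stood at 5.21 ± 0.14, the catalytic subunit gene Psmb5 at 7.82 ± 0.28, the immunoproteasome subunit gene Psmb8 at 6.97 ± 0.29 and Psmd14 at 3.47 ± 0.33 (SD, n = 4 each). Of 13 heat shock and chaperone genes 10 passed (exact test, adjusted p = 0.0137). Hspa8, a constitutive chaperone, stood at 9.51 ± 0.14 (SD, n = 4), and Hspb1 passed on 2 of 4 arrays. Of 19 genes of the unfolded protein and integrated stress responses 16 passed (exact test, adjusted p = 0.000226). Hspa5, the chaperone of the endoplasmic reticulum, stood at 5.35 ± 0.16, Trib3 at 5.13 ± 0.37 and Atf3 at 2.12 ± 0.21 (SD, n = 4 each). Ddit3, which encodes the stress transcription factor CHOP, stood at 4.15 ± 0.68 (SD, n = 4) with replicate 2 at 3.13 and the other arrays between 4.38 and 4.57. Its spot also lay in the area of lowered signals on the replicate 2 array.

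Of 23 cholesterol biosynthesis genes 17 were well above background on all 4 arrays (Fisher's exact test, adjusted p = 0.00192). Hmgcs1 and Sqle, enzymes early and midway in the pathway, stood at 2.06 ± 0.35 and 2.38 ± 0.22 (SD, n = 4 each). Of 22 lysosome genes all passed (exact test, adjusted p = 7.52e-09), with Ctsd at 9.97 ± 0.16, Lamp1 at 5.79 ± 0.17 and the cholesterol-binding Npc2 at 5.18 ± 0.30 (SD, n = 4 each).

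Of 18 hypoxia response genes 15 were well above background on all 4 arrays (Fisher's exact test, adjusted p = 0.000414). The glucose transporter gene Slc2a1 stood at 5.69 ± 0.16 and Hif1a, the oxygen-regulated transcription factor, at 3.04 ± 0.39 (SD, n = 4 each), while Vegfa and Egln3 passed on no array. Of 17 p53 target and apoptosis genes 11 passed (exact test, adjusted p = 0.0552). In the 7 alternatives the adjusted p of the exact test lay between 0.0520, without replicate 2, and 0.607, when all probes of a gene had to pass. The cell cycle inhibitor gene Cdkn1a stood at 5.27 ± 0.19, Gadd45a at 2.67 ± 0.25 and Mdm2 at 1.66 ± 0.13 (SD, n = 4 each). All 18 measured cell cycle genes passed (exact test, adjusted p = 1.69e-07), with the proliferation marker Mki67 at 3.59 ± 0.46 and Pcna at 4.71 ± 0.14 (SD, n = 4 each). Hif1a and Cdkn1a each had 2 probes, of which 1 was well above background on all 4 arrays. The named genes Cd79a, Mpo, Hspa1b, Dnajb1 and Top2a had no probe that could be tied to their symbol.

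**Figure D2:**
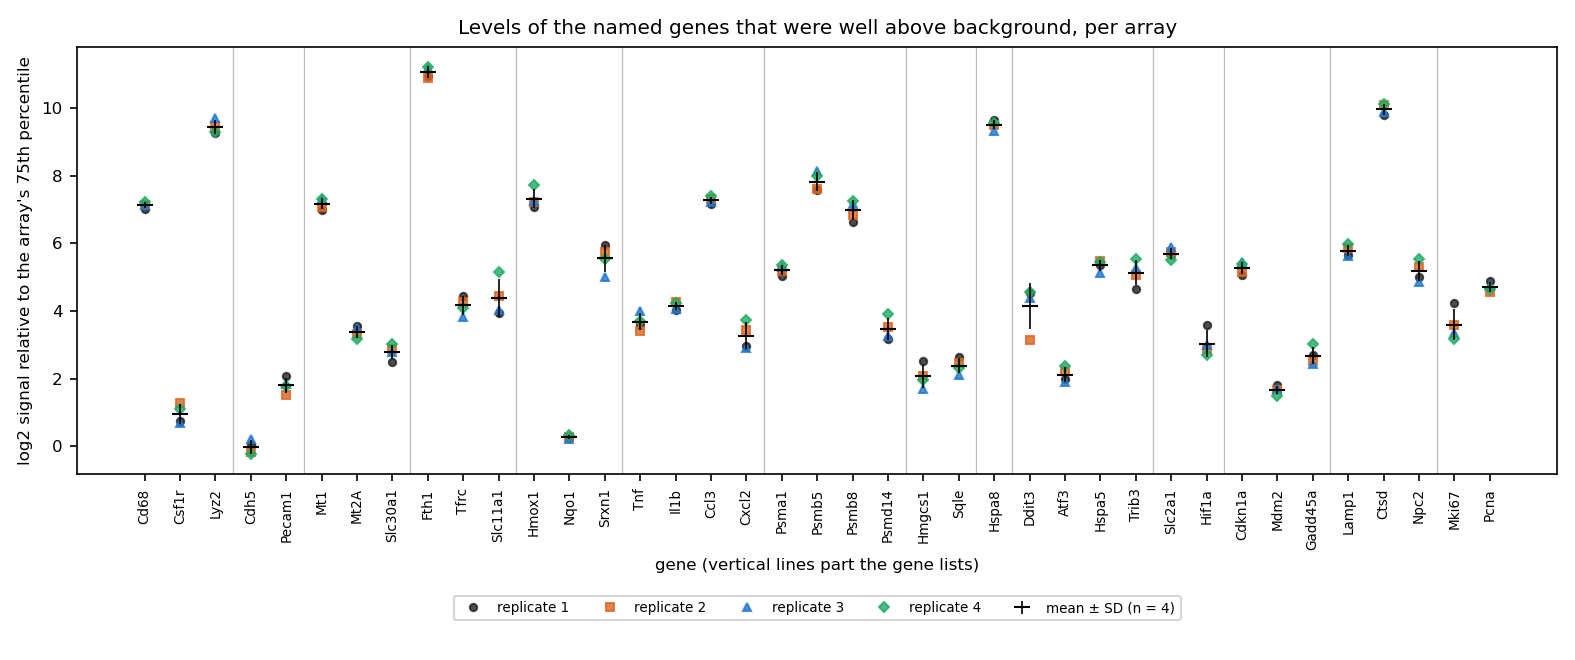
Points give the log2 signal relative to the 75th percentile of the array, with 1 symbol per replicate. Drawn are the genes named in advance from the fixed lists that were well above background on all 4 arrays. Genes picked for the largest SD and genes of the lists added later are not drawn. Bars give the mean ± SD (n = 4) and vertical lines part the gene lists. Ddit3 on replicate 2, at 3.13 against 4.38 to 4.57 on the other arrays, stands apart.

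The spread between replicates set how finely levels could be told apart. The median SD per gene was 0.23 log2 units over the 6418 genes, with the 10th and 90th percentiles at 0.10 and 0.43. An SD above 0.5 was found for 368 genes (5.73%). Genes with a large SD included Cebpg, Zfyve21, Basp1, Uckl1, Rn18s, mrpl11, Tmem86a, Fbxw2 and Grin2d, with SDs from 1.56 down to 1.23. For 4 of them, Cebpg, Uckl1, mrpl11 and Tmem86a, replicate 2 was far below the rest, as for Cebpg, a bZIP transcription factor gene, at 0.31 against 2.98 to 3.60. For Zfyve21 and Fbxw2 it was replicate 4, at -0.23 against 2.55 to 2.83 and at 1.61 against 3.94 to 4.20. Rn18s, the 18S ribosomal RNA gene, stood at 5.04 on replicate 1 and between 7.15 and 8.13 on the others.

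The positions of the deviating spots were not even across the arrays. On replicate 2, 211 of 10000 spots of probes printed in a single spot lay more than 1 log2 unit below the median of the other 3 arrays. Of these, 139 formed a chain in which each spot lay within 5 rows and 5 columns of the next, against at most 9 in 1000 random draws of as many spots. The chain spanned rows 155 to 219 and columns 72 to 94, an area with 2.4% of the spots tested and 154 named genes, where the median deviation was -1.12 log2 units. Cebpg, Uckl1, mrpl11 and Tmem86a had their spots in the chain, as had Ddit3 and the proteasome gene Psmc3, whose spot was 2.34 log2 units below the median of the other arrays. On replicate 4 the longest chain had 12 spots, the Zfyve21 and Fbxw2 spots among them, against at most 9 in random draws.

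**Figure D3:**
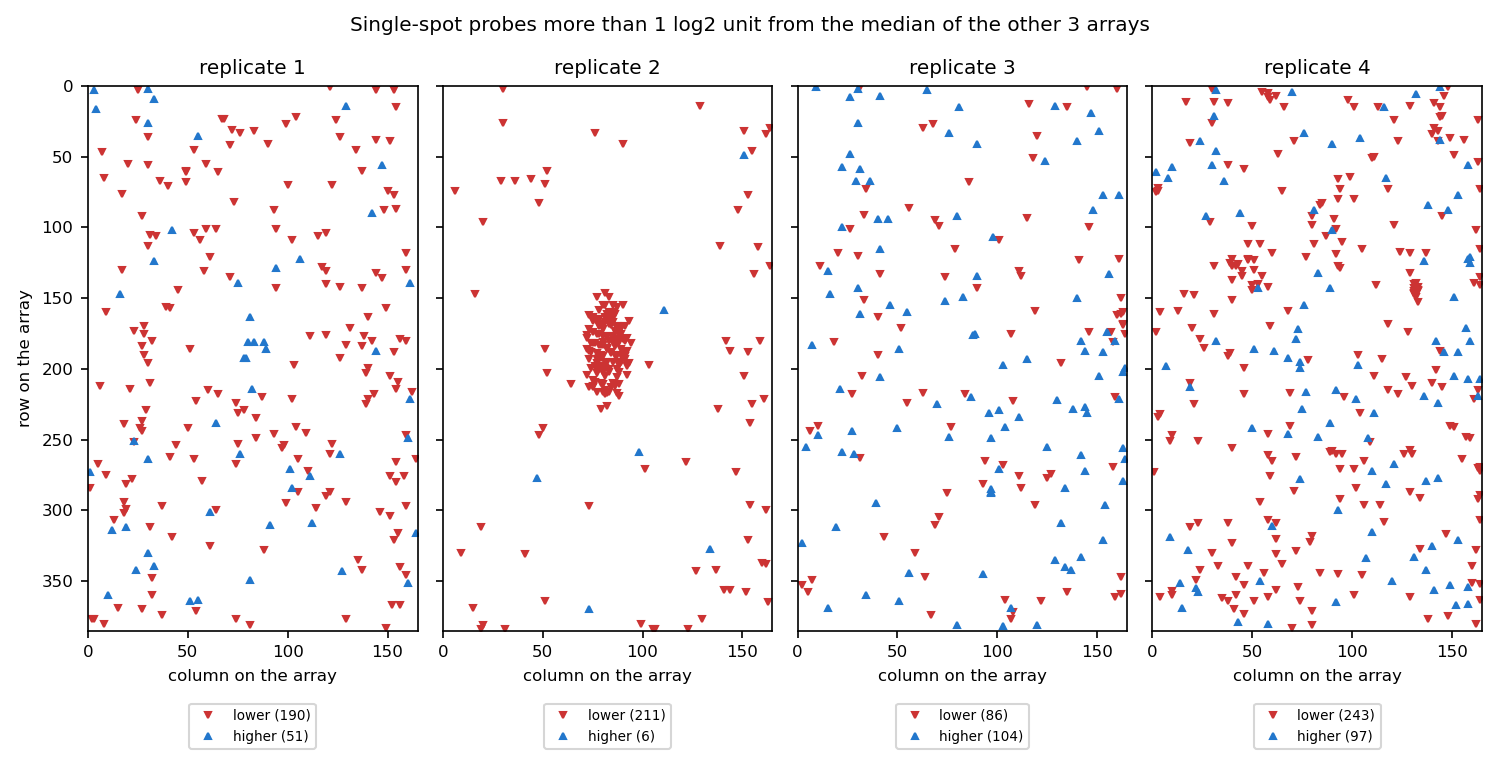
Each panel is 1 array drawn by spot row and column, with a mark for every single-spot probe that lay more than 1 log2 unit below (red, pointing down) or above (blue, pointing up) the median of the other 3 arrays; the legends give their numbers. On replicate 2, 139 of the 211 lower spots form a chain in rows 155 to 219 and columns 72 to 94.

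Gene groups were then compared with random lists of the same size and signal. Of 14 lists with at least 3 members above background, 3 lay outside the central 95% of 10000 random lists in 1 of 2 measures of spread. The 22 lysosome genes had a median SD of 0.26, above that of 98.7% of the random lists. The mean of the 16 unfolded protein and integrated stress response genes differed between arrays with an SD of 0.17, at percentile 97.53, and deviated by -0.18, -0.10, 0.12 and 0.16 on replicates 1 to 4. This call turned with the scaling: the list mean lay at percentile 1.01 without scaling and 1.89 with spike-in centring, where it varied less than in random lists, and inside the limits at 93.2 with quantile normalization, 90.7 with the percentile over detected probes and 94.2 with the local trend removed. It also fell inside when any replicate was left out (93.9, 97.3, 87.3 and 97.1 without replicates 1 to 4) and with the mean of all probes (92.7). The mean of the 15 hypoxia response genes varied less than in most random lists, with an SD of 0.01, at percentile 0.71. It lay inside the limits under every other scaling, at percentile 50.3 with quantile normalization, 62.9 with the percentile over detected probes, 85.6 without scaling and 86.0 with spike-in centring. It stayed outside them with the local trend removed (0.54), without replicate 2 (1.94) and without replicate 3 (0.88), and not without replicate 1 (4.16), without replicate 4 (5.33) or with the mean of all probes (23.3). Neither list mean differed from random lists in a way that held across settings. The lysosome genes stayed above the limit with quantile normalization (99.7), the percentile over detected probes (99.7), no scaling (98.1) and no filter on dim probes (98.9). They did not with spike-in centring (58.5), with the mean of all probes (96.7), without replicate 1 (96.2) or without replicate 4 (95.9). Random lists gave 1.30 lists outside these limits on average, and a share of 0.13 of 1000 sets of random lists had as many as 3. No list lay outside when the signals were corrected with the normexp method. The offset added in that method alters spreads by itself, and its share in this result was not tested.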

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

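The position test, the test on probes in 10 spots and the random sets of lists were fixed before their results were seen; the chains of neighbouring spots, the additional gene lists and the split of the macrophage markers were chosen after.

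On the replicate 2 array 211 single-spot probes lay more than 1 log2 unit below the other 3 arrays, and the genes Cebpg, Uckl1, mrpl11, Tmem86a, Psmc3 and Ddit3 were among them. A local defect of the array surface may account for this pattern: 73.9% of these spots had another within 5 rows and 5 columns, against a median of 32.2% and an upper limit of 40.8% in 1000 random draws of as many spots. Lower spots also lay together more than their random upper limit on replicates 1 (40% against 37.9%), 3 (27.9% against 23.3%) and 4 (45.3% against 43.0%). Some clustering may therefore not be particular to replicate 2. The limits for replicates 1, 3 and 4 came from only 100 draws each, so these margins are uncertain. For all 211 spots a lower transcript level in the cells of that flask cannot be told apart by the test on probes in 10 spots. None of 974 such probes deviated, with an exact 95% upper limit of 0.378% against 2.11% of single spots, but the limit also lay below the single-spot share on replicates 1 (0.740% against 1.91%), 3 (0.735% against 0.819%) and 4 (0.736% against 2.34%). For the 139 spots of the longest chain it is argued against, because random draws gave chains of at most 9 spots and the longest chains on replicates 1, 3 and 4 had 5, 3 and 12. With the local trend removed, the SD of Cebpg went from 1.56 to 0.80, of Ddit3 from 0.68 to 0.26 and of Psmc3 from 1.16 to 0.37. Whether single genes inside the area also differed in the cells stays open.

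Of 87 values tested for 1 array apart from the other 3, 5 exceeded Dixon's 95% critical value, where chance gives about 1 in 20. Zfyve21, Uckl1 and Fbxw2 among them come from the 10 genes picked for the largest SD, so that rate is not their baseline. Over all 6418 genes above background 316 (4.92%) exceeded it, which is near the chance rate. Ddit3 (Dixon's ratio 0.863) and Uckl1 (0.857) were low on replicate 2 within the area just described. Zfyve21 (0.906) and Fbxw2 (0.897) were low on replicate 4, and their spots lie in the chain of 12 lower spots on that array. The rectangle around that chain, drawn from it, held 15 single spots with a median deviation of -2.56. The spots within 10 rows and columns of the genes had medians of -0.01 and 0.00, and the SDs were 1.43 and 1.21 with the trend over that window removed, which is wider than the chain. The cause is left open. Fabp4 (0.832) was high on replicate 2, at 2.85 against 2.77 to 2.78.

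The arrays carry control probes for synthetic ERCC transcripts, which no comparison used. The probe for ERCC-00148 was well above background in 139 of its 140 spots over the 4 arrays, against 1 of 1232 negative control spots.

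Of the 9 macrophage markers that were not well above background on all 4 arrays, 2 were positive and significant under the looser flag, Mrc1 and Msr1, which leaves open whether the strict flag accounts for the group. Of the 7 markers above background on no array, Marco, Cd163, Adgre1, C1qa, C1qb, C1qc and Csf2rb, 0 passed under the looser flag, but this group was picked by the strict flag itself, so the count excludes nothing. A probe that does not report its transcript cannot be told apart from a low level, because 0 of the 9 markers had more than 1 probe. A lowering by the exposure cannot be told apart either, with 0 arrays of unexposed cells analysed here.

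Of the 14 gene lists, 3 lay outside the random lists in their spread. Chance may account for this count, since the share of random sets with as many was 0.13.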

How the results depend on the processing

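Of the 13 lists called by their share above background, 11 kept their side of the threshold under the 7 alternatives run for them: the looser flag, 3 of 4 arrays, all probes of a gene and the omission of each replicate. The granulocyte and mast cell list was no longer past it when all probes of a gene had to pass (1 member, adjusted p = 0.0939 by Fisher's exact test), and the iron handling list was not when 3 of 4 arrays sufficed (12 members, adjusted p = 0.0722); fewer or more of the other genes then passed. The median SD between arrays was 0.23; it was 0.38 without scaling, 0.57 with spike-in centring, 0.43 with no filter on dim probes, 0.19 with normexp, 0.17 for probes in 10 spots, and 0.20 to 0.24 without 1 replicate. The 368 genes with an SD above 0.5 became 1749 without scaling, 4209 with spike-in centring, 4081 of 16578 with no filter, 132 with normexp and 9 of 447 for probes in 10 spots; without 1 replicate there were 317 to 546. Spike-in centring moved arrays by between -0.54 and 0.73 log2 units relative to the 75th percentile, and no scaling by between -0.34 and 0.48, so a level holds only relative to the 75th percentile. The 3 lists outside the random lists became 4 without scaling, 2 with quantile normalization, 1 with spike-in centring, 1 with the mean of all probes, 0 with normexp and 0 for probes in 10 spots, and 2 to 3 without 1 replicate, and the lists that make up the count also changed; the cause was not tested. With the local trend removed 298 genes had an SD above 0.5, of which 241 were among the 368. Levels of the 49 named genes above background moved by more than 1 SD with normexp (44 moved) and the mean of all probes (8 moved). They did not in the other 9 settings run for levels. In 3 of those, no scaling, spike-in centring and the percentile over detected probes, the mean over arrays cannot move since array offsets are centred. Leaving out 1 of 4 arrays cannot move the mean of the same probe by more than 1 SD either. Those settings therefore say nothing about how stable the levels are. The normexp setting adds an offset of 50 to every signal. By itself this lowers log2 levels that lie above the 75th percentile, and it alters their SD. The 44 moved levels therefore do not show that levels are unstable. The median SD of 0.19, the 132 genes and the 0 lists with normexp do not show a gain in precision. Levels were not run for probes in 10 spots, for no filter on dim probes, or for the genes of the lists added after seeing the data.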

Other observations

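A set of 6 further gene lists was drawn up after the main values had been seen, and describes biology outside the lists fixed in advance. Lipid uptake and efflux genes were widely present, with 13 of 15 well above background on all 4 arrays (Fisher's exact test, adjusted over these 6 lists, p = 0.000563). The fatty acid receptor gene Cd36 stood at 7.29 ± 0.22, the transcription factor gene Pparg at 5.54 ± 0.07, the lipid droplet gene Plin2 at 5.37 ± 0.27 and Fabp4 at 2.79 ± 0.04 (SD, n = 4 each), while Apoe passed on 2 of 4 arrays. All 17 measured cytosolic ribosomal protein genes passed (exact test, adjusted p = 5.82e-07), with Rpl3 at 9.47 ± 0.12, Rpl32 at 10.78 ± 0.13 and Rps6 at 7.88 ± 0.10 (SD, n = 4 each).

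Of 15 antigen presentation genes 7 passed (exact test, adjusted p = 0.719). B2m, the light chain of class I molecules, stood at 8.21 ± 0.04 (SD, n = 4), while Cd74, RT1-Da and the class II regulator gene Ciita passed on no array. Of 18 pattern recognition and inflammasome genes 9 passed (exact test, adjusted p = 0.627), with Tlr2 at 3.71 ± 0.13, Pycard at 2.79 ± 0.20, Casp1 at 2.27 ± 0.08 and Tlr4 at 1.19 ± 0.23 (SD, n = 4 each); Tlr2 and Tlr4 are also in the macrophage list. Of 14 matrix protease and inhibitor genes 7 passed (exact test, adjusted p = 0.627), with Timp2 at 8.68 ± 0.17, Mmp9 at 2.45 ± 0.41 and Mmp12 at 1.78 ± 0.56 (SD, n = 4 each), and Timp1 on no array. Of 14 chemotactic receptor genes 5 passed (exact test, adjusted p = 1), with C5ar1 at 2.70 ± 0.22 and Ccr1 at 1.72 ± 0.48 (SD, n = 4 each), and neither Ccr2 nor Cxcr4 on any array.

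Among the genes with the largest SD, Basp1 stood at 10.57, 9.23, 12.09 and 8.85 on replicates 1 to 4, and Grin2d at 10.55, 9.70, 12.14 and 9.39. The spots around them deviated by at most 0.23 log2 units in median.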
